A study of Danio rerio with 4 samples.

How the data were processed

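Total RNA had been extracted with Trizol from whole 7 dpf zebrafish embryos that were genotyped as tubgcp6 mutants or siblings, and libraries had been made with a NEBNext Ultra RNA kit, per the labels' protocols. The authors deposited 1 table of raw read counts per gene, with a column for each of 4 libraries, and the values are whole numbers with no normalization. The submitters' processing notes name fastp 0.23.2, STAR 2.7.10a, featureCounts 2.0.1, R 4.2.2, DESeq2 1.26.0 and the genome build GRCz11, without saying in which order or for what each was used. The gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. It is therefore not known whether reads from overlapping genes on opposite strands were told apart, and genes with near-identical copies (globins, gamma-crystallins, jacalin genes) carry an uncertain split of reads.

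The table held 23236 rows under 22976 gene names. Of these names, 125 stood on more than 1 row (385 rows in all) and were kept out of the gene lists, and 17 rows had a name made of digits only, held between 0.0574% and 0.0626% of a library's counts, and are not named. In all libraries 771 rows were 0. The mitochondrial gene COX1 took the largest share of counts in each library (2.04% to 2.33%). Gene names were looked up in a RefSeq table of the assembly GRCz12tu, where 20334 matched a symbol and 1003 a synonym; since that assembly is not GRCz11, it was used only for synonyms, for the chromosome that a gene lies on and for which genes neighbour each other, and no coordinates are given.

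Groups and replicate numbers were taken from the labels. Counts were tested in R 4.3.3 with edgeR 4.0.16: rows with low counts were removed with filterByExpr at its defaults (3139 rows), libraries were scaled with TMM, and each gene was tested for a difference between mutants and siblings with the quasi-likelihood F-test (glmQLFit with legacy=FALSE, glmQLFTest). P-values were adjusted by the Benjamini-Hochberg method over the 20097 genes tested, with a threshold of 0.05. Standard errors of log2 fold changes were taken as the size of the log2 fold change divided by the square root of its F statistic. CPM values were computed from the TMM-scaled library sizes and are given as mean ± SD. The common dispersion corresponded to a biological coefficient of variation of 7.19%. For genes with 10 or fewer counts in a group, a ratio of counts per scaled library was also computed, with a 95% interval from the exact binomial distribution, which covers counting error only.

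The 33 gene lists, with 911 entries, cover blood lineages, the gamma-tubulin complex and centrosomes, cell division, inflammation, stress and the main tissues of an embryo; 882 entries matched a name in the table, 21 of them through a RefSeq synonym. Each list was tested two-sided with camera (limma 3.58.1) with a correlation between genes preset at 0.01, adjusted over the lists. Camera with the correlation estimated for each list, and fry, were run beside it. The estimated run takes its degrees of freedom from the 4 libraries and the preset run from the genes. The estimated run can therefore hardly reach low p-values. Camera compares the members of a list with the other tested genes, whereas fry asks only whether the members differ between groups. In 3 lists 1 member had 3 or fewer counts in a group, and placing that member at the limit of its counting interval moved no list's median. Called lists kept the sign of their median under both other scalings. The genes named were chosen by a rule set before the data were examined. They are tubgcp6; the 12 rises and the 12 falls of largest size among genes past the threshold with an average log2 CPM of at least 1, both mutant libraries on the same side of both sibling libraries, and an assigned gene symbol; up to 4 members of each list with the smallest p; and any member of the HSPC and gamma-tubulin lists. Exceptions are stated where they occur. The result of 1 list and the values of some genes are not reported here. The share of called genes on the chromosome of tubgcp6 was tested with Fisher's exact test.

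The gene test and the list test were tested on simulated counts, drawn for each gene independently. The draws used the means and library sizes of these libraries and the trend of dispersion over expression. Dispersion was the same in both groups and genes did not scatter around the trend, so the setting was cleaner than the data. Of the 20097 genes drawn, 19940 passed the filter on average. For the gene test 200 genes were changed by known folds, and for the list test only the members of 1 list. Of the genes changed 1.25-fold, 15.3% were called; this rose to 50.0% at 1.5-fold, 90.7% at 2-fold and 99.3% at 4-fold, and 5.43% of all calls were genes left unchanged. Of unchanged lists 3% had an unadjusted p under 0.05, and of lists raised 1.5-fold 100%. As genes were drawn independently, these shares do not cover lists whose genes move together. The shares of the gene test hold for few changed genes, whereas 43.89% of the tested genes were called in the real data.

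The alternatives tried were the relative-log scaling of DESeq2, DESeq2 1.42.0 itself, limma-voom, the older quasi-likelihood fit of edgeR, no filter on low counts, scaling without the 20 most abundant genes, the replicate number as a block, leaving out each library in turn, and leaving out the genes on the chromosome of tubgcp6. A test against a fold of 1.5 (glmTreat) and the chromosome share among genes called at 2-fold or more were added after seeing the data. With 1 library left in a group, that library is assumed to vary as the other group does.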

Results

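RNA was sequenced from whole zebrafish (Danio rerio) embryos of the AB laboratory strain at 7 days post fertilisation (dpf). Crosses between tubgcp6 heterozygotes had been sorted by genotype into mutants and siblings. The gene tubgcp6 encodes a subunit of the gamma-tubulin ring complex, which nucleates microtubules at centrosomes and spindles. Each group had 2 libraries, numbered as biological replicates; whether the groups shared clutches was not stated, so p-values measure the spread between these libraries. The sibling genotypes and the lesion in tubgcp6 were not stated either. Reads assigned to genes totalled 17074352 and 17833761 in the mutant libraries and 14246582 and 20652276 in the sibling libraries. Replicates differed by more than counting noise, with a chi-square per degree of freedom of 5.75 between the mutant libraries and 2.76 between the sibling libraries. The title of the series sets the question in the context of hematopoietic stem and progenitor cells (HSPCs), and the design holds 1 comparison, mutants against siblings.

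The mutated gene was read at a moderately lower level in mutants. The counts of tubgcp6 were 510 and 531 in the mutant libraries and 498 and 803 in the sibling libraries, or 29.7 ± 0.639 CPM (counts scaled to a common library total) in mutants and 37.1 ± 2.59 CPM in siblings (SD, n = 2 each). Its log2 fold change (mutant over sibling throughout) was -0.33 ± 0.10 (SE), with an adjusted p of 0.0123 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The call did not hold in DESeq2, where the adjusted p was 0.0585, nor in edgeR without sibling replicate 2, where the log2 fold change was -0.25 and the adjusted p 0.267.

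Mutant embryos had higher RNA levels of most tested genes of cell division, DNA replication and inflammation, and lower levels of most tested lens, photoreceptor, exocrine pancreas and lymphoid genes. As lists these were called with a preset correlation between genes and not with an estimated one. With 4 libraries the test with an estimated correlation can hardly reach the threshold. Proliferation marker mki67 stood at 132 ± 12.7 CPM in mutants and 46.8 ± 1.17 CPM in siblings (SD, n = 2 each). Rod opsin gene rho stood at 52.3 ± 5.88 CPM in mutants and 528 ± 36.5 CPM in siblings. Lymphocyte recombinase gene rag1 stood at 3.70 ± 0.0565 and 13.8 ± 0.520 CPM. Of 20097 genes tested, 4595 were higher and 4226 lower in mutants at an adjusted p under 0.05 in edgeR's quasi-likelihood test; 1252 of the higher and 869 of the lower genes differed at least 2-fold. Without sibling replicate 2 the spread came from the 2 mutant libraries alone, and the test called fewer genes in both directions.

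**Figure D1:**
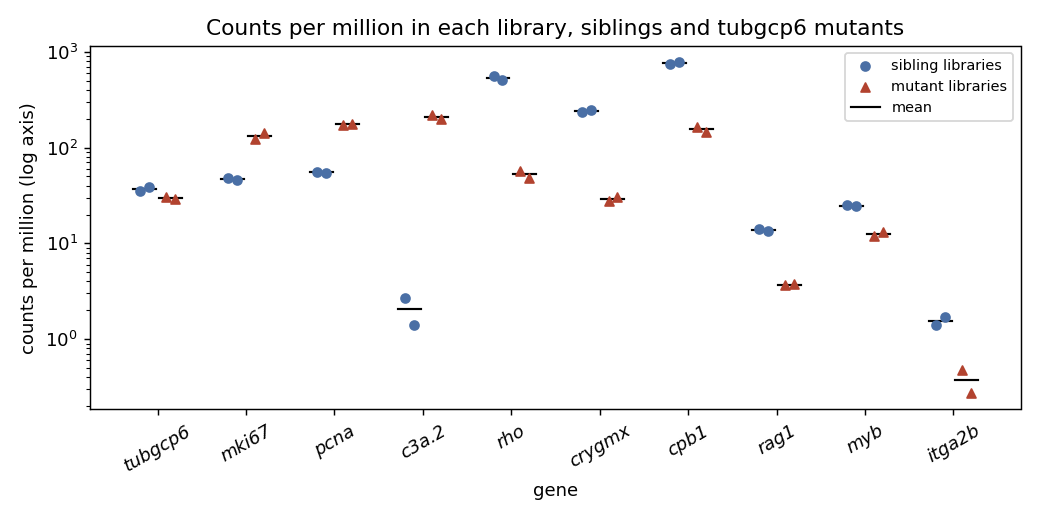
CPM (log axis) of 10 genes in each of the 2 sibling libraries (circles) and 2 tubgcp6 mutant libraries (triangles), with the group mean as a line. Both mutant libraries lie above both sibling libraries for mki67, pcna and c3a.2 and below them for the other genes shown.

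The 12 genes picked by the size of the rise included leptin and complement genes. Leptin gene lepb had 326 and 258 counts in mutants against 0 and 2 in siblings, a ratio of 289 with a 95% counting interval of 79.7 to 2390, and the second leptin gene, lepa, rose by 4.79 ± 0.46 (log2 fold change ± SE). Complement genes c3a.2 (6.74 ± 0.15) and c4b (5.32 ± 0.13) rose, as did cytokine gene il11a (4.78 ± 0.36), intelectin gene itln3 (4.75 ± 0.36), heme-binding hemopexin gene hpxa (4.27 ± 0.34), serpin gene serpina7 (5.47 ± 0.16), metalloproteinase inhibitor gene timp2b (4.2 ± 0.14) and ribonuclease gene rnasel3 (3.96 ± 0.21). The jacalin family genes jac8 (5.35 ± 0.49) and jac9 (5.14 ± 0.34) rose too, with reads that near-identical copies can share. Single libraries moved some of these values. Without sibling replicate 1 the log2 fold change was 7.33 for lepb, 6.49 for lepa, 6.07 for serpina7, 6.16 for jac8 and 8.13 for jac9. Without sibling replicate 2 it was 3.78 for lepa, 4.65 for jac8 and 3.97 for jac9. For lepb the fit then gave 11.098, but with 0 sibling counts left the size of this value is not determined by the data. Without mutant replicate 1 it was 4.51 for jac8.

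The 12 genes picked by the size of the fall included lens and photoreceptor genes. The gamma-crystallin gene crygm2e, 1 of many similar copies, had 1 and 3 counts in mutants against 70 and 109 in siblings, a ratio of 0.0221 with a 95% counting interval of 0.00597 to 0.0577. Lens genes grifin (-4.25 ± 0.20), lim2.5 (-3.56 ± 0.19), crygm7 (-3.44 ± 0.42) and lctlb (-3.21 ± 0.18) fell, as did the outer segment gene rom1b (-3.54 ± 0.24) and rho (-3.33 ± 0.10). The other falls were in csf1rb, a receptor gene of macrophages and related cells (-5.07 ± 0.42), the mineralised tissue gene scpp5 (-4.86 ± 0.32), cathepsin gene ctsbb (-4.22 ± 0.17), cerebellin family gene cbln12 (-3.50 ± 0.31) and the endocytic receptor gene lrp2b (-3.15 ± 0.19). Without mutant replicate 2 the log2 fold change was -6.28 for crygm2e, -4.89 for ctsbb and -3.73 for lrp2b. Without mutant replicate 1 it was -4.42 for cbln12.

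For 33 tissues and processes, lists of genes were written before the data were examined. The test camera, run on the edgeR fit with a preset correlation between genes, called 10 lists higher and 9 lower in mutants. With the correlation estimated for each list, 0 of these 19 lists passed an adjusted p of 0.05, and 6 passed at an unadjusted p under 0.05. The loss was not only a matter of higher correlation: the estimates for the intestine (-0.039) and lymphoid (-0.016) lists were below the preset 0.01. The degrees of freedom of that test come from the 4 libraries, which keeps its p-values high. Even the lens list, where 25 of 26 genes fell, had an unadjusted p of 0.0259 in it. The lost calls therefore cannot decide for or against these lists. The preset run can in turn give p-values that are too small where genes move together. In 23 of the 33 lists the counts of genes that rose and fell were the same when adjusted over the list alone; of the other 10, those reported are given with both counts. Members named as moving against their list were singled out after their values were seen. Counts of 4 or fewer moved by up to 5 genes when 1 library was left out.

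Cell cycle genes rose almost without exception. Of 51 mitosis genes, 50 rose, 0 fell and 1 did not pass, with a median log2 fold change of 1.5 (camera adjusted p = 2.53e-34, or adjusted p = 0.229 with an estimated correlation). Cytokinesis gene anln rose by 2.26 ± 0.13 (SE), spindle motor gene kif11 by 1.89 ± 0.12 and mitotic kinase gene plk1 by 1.70 ± 0.12. Of 54 DNA replication genes, 52 rose and 1 fell, or 53 and 1 adjusted over the list alone, with a median of 1.29 (camera adjusted p = 3.27e-24, or adjusted p = 0.229 with an estimated correlation). Replication clamp gene pcna rose by 1.67 ± 0.09, and helicase genes mcm2 and mcm3 by 1.65 ± 0.12 and 1.81 ± 0.13. The 1 replication gene that fell was mcm7, a further helicase subunit gene (-0.53 ± 0.08).

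Genes of microtubule nucleation were mixed. Of 17 genes of the gamma-tubulin ring complex and the augmin complex that recruits it, 8 rose, 2 fell and 7 did not pass, with a median of 0.36, and the list was not called by camera (adjusted p = 0.175) but was called higher by fry (adjusted p = 0.0148). The genes that rose were mostly augmin subunits, among them haus5 (1.43 ± 0.25), haus1 (1.37 ± 0.30) and haus3 (1.23 ± 0.26); the 2 that fell were tubgcp6 and cdk5rap2 (-0.55 ± 0.10), a gene of a centrosome protein that recruits the complex. Of 18 centriole and centrosome genes, 8 rose and 3 fell (median 0.18, camera adjusted p = 0.59), a median of 0.337 without mutant replicate 1 and 0.08 without mutant replicate 2, with cep152 at 1.04 ± 0.19 and cep290 at -1.10 ± 0.10.

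The HSPC list was not called as a set. Of 21 genes, 6 rose, 8 fell and 7 did not pass, or 6 and 9 adjusted over the list alone; the mean log2 fold change was -0.32 and the median -0.24 (camera adjusted p = 0.439), or -0.128 without sibling replicate 1 and -0.127 without sibling replicate 2. Without sibling replicate 2 only 2 rose and 2 fell, and without sibling replicate 1 or mutant replicate 1 only 5 fell. Transcription factor gene myb, needed for definitive blood stem cells, fell by 0.97 ± 0.13, from 24.7 ± 0.401 CPM in siblings to 12.6 ± 0.861 CPM in mutants (SD, n = 2 each). The HSPC and thrombocyte integrin gene itga2b fell by 2.07 ± 0.48 at low counts. Transcription factor gene gata2b changed by -2.40 ± 0.58 at a total of 8 counts in mutants and 43 in siblings, and its call was lost without sibling replicate 2, where edgeR's quasi-likelihood test gave an adjusted p of 0.0602. Without mutant replicate 2 it was at -3.31. Of the list, lin28a (1.09 ± 0.26) and hmga2 (0.56 ± 0.11) rose, whereas lin28b, a paralogue of lin28a outside the list and singled out after its values were seen, was lower (-1.01 ± 0.20). The change of runx1, a regulator of blood stem cell emergence, was 0.54 ± 0.27 with an adjusted p of 0.0985 in edgeR's quasi-likelihood test; without mutant replicate 1 it was 0.79 with an adjusted p of 0.0172, and without mutant replicate 2 it was 0.21.

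Among differentiated blood lineages the lymphoid list was lower. Of 27 lymphoid genes, 19 fell, 1 rose and 7 did not pass, with a median of -0.73 (camera adjusted p = 9.11e-06, or adjusted p = 0.226 with an estimated correlation). The thymus homing receptor gene ccr9a (-2.32 ± 0.22), rag1 (-1.89 ± 0.18) and the T cell transcription factor gene bcl11ba (-0.73 ± 0.09) fell, whereas tnfrsf9a, an activation-induced receptor gene, rose by 1.42 ± 0.27. Of 6 thymic epithelium genes, 2 rose and 1 fell (median 0.12, or -0.191 without sibling replicate 2 and -0.163 without mutant replicate 1; camera adjusted p = 0.429). The gene foxn1, the regulator of that tissue, singled out after its values were seen, was at -0.54 ± 0.33 and chemokine gene ccl25a at 0.25 ± 0.13, both short of the threshold, while ccl25b rose by 1.06 ± 0.10. Of 26 erythroid genes, 12 fell, 3 rose and 11 did not pass (median -0.32, camera adjusted p = 0.00508, or adjusted p = 0.229 with an estimated correlation), with embryonic globin gene hbbe2 at -1.26 ± 0.10, a value that similar globin copies make uncertain. Of 11 thrombocyte genes, 4 rose and 3 fell (median -0.015, camera adjusted p = 0.866); thbs1b was at 0.51 ± 0.08 and fermt3b at -2.21 ± 0.41, or -2.81 without mutant replicate 2.

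Myeloid genes did not move as a block. Of 20 neutrophil genes, 8 rose, 5 fell and 7 did not pass; the list was called higher (camera adjusted p = 0.0284, or adjusted p = 0.438 with an estimated correlation) with a mean of 0.22 but a median of -0.14. That median was -0.009 without mutant replicate 1, 0.125 without mutant replicate 2 and -0.079 without sibling replicate 2. The call was lost without sibling replicate 2 (adjusted p = 0.0516) and with fry (adjusted p = 0.0613). Chemotactic factor gene lect2l rose by 3.68 ± 0.15 and matrix metalloproteinase gene mmp9 by 2.78 ± 0.11, while carboxypeptidase gene cpa5 fell by 1.27 ± 0.09. Of 26 macrophage genes, 11 fell and 3 rose, or 11 and 4 adjusted over the list alone (median -0.33, or -0.55 without mutant replicate 2; camera adjusted p = 0.175). Apolipoprotein gene apoeb rose by 1.72 ± 0.09, while lcp1, an actin-bundling gene of leukocytes, fell by 1.54 ± 0.15, and csf1rb was at -5.07.

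Inflammation and acute-phase genes rose. Of 23 inflammation genes, 18 rose, 0 fell and 5 did not pass, with a median of 1.43 (camera adjusted p = 4e-27, or adjusted p = 0.229 with an estimated correlation). The C-reactive protein gene listed as si:ch211-270n8.1 rose by 8.34 ± 0.23 from 7 and 2 counts in siblings (9.70 without sibling replicate 1, 7.42 without sibling replicate 2), complement factor gene cfb by 3.02 ± 0.10 and immunometabolic enzyme gene irg1l by 3.92 ± 0.15; mmp9 is on this list as well as the neutrophil list. Of 30 liver genes, 17 rose and 8 fell (median 0.46, camera adjusted p = 9.27e-11, or adjusted p = 0.226 with an estimated correlation). The rises included complement gene c9 (3.03 ± 0.09) and fibrinogen genes fgb (2.59 ± 0.10) and fga (2.2 ± 0.09), and the largest was that of hpxa (4.27 ± 0.34). Of 22 interferon genes, 11 rose and 2 fell (median 0.60, camera adjusted p = 0.0792; called higher without sibling replicate 2, adjusted p = 0.041, and with fry, adjusted p = 0.0175), with stat1b at 2.04 ± 0.27, irf9 at 1.17 ± 0.13 and the feedback inhibitor gene socs1a at -1.17 ± 0.14.

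Stress lists were higher too. Of 28 genes of endoplasmic reticulum (ER) stress, 18 rose and 1 fell, or 21 and 1 adjusted over the list alone (median 0.61, camera adjusted p = 3.96e-11, or adjusted p = 0.317 with an estimated correlation). The genes that rose most clearly encode ER chaperones, among them pdia4 (2.06 ± 0.10), calr3b (1.90 ± 0.10), hsp90b1 (1.67 ± 0.09) and hspa5 (1.51 ± 0.09). The gene ddit3, of a transcription factor of prolonged ER stress, changed by -0.27 ± 0.09, a call that edgeR's quasi-likelihood test lost without sibling replicate 1 (adjusted p = 0.0785) or without sibling replicate 2 (adjusted p = 0.203). Of 24 genes of handling stress, meaning heat shock and immediate early genes, 16 rose and 2 fell, or 17 and 2 adjusted over the list alone (median 0.53, camera adjusted p = 0.000165, or adjusted p = 0.408 with an estimated correlation). That median was 0.316 without mutant replicate 1, and the call was lost with fry (adjusted p = 0.0873). The heat shock gene hspb1 rose by 1.60 ± 0.11 and the immediate early gene junba by 1.58 ± 0.14.

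The eye and the pancreas accounted for the lists with the lowest medians. Of 26 lens genes, 25 fell and 1 rose, with a median of -2.19 (camera adjusted p = 2.23e-74, or adjusted p = 0.226 with an estimated correlation); the falls included gamma-crystallin gene crygmx (-3.06 ± 0.09), beta-crystallin gene cryba2b (-2.59 ± 0.10) and water channel gene mipa (-2.88 ± 0.10), while crygs1 rose by 1.91 ± 0.34, or 1.32 without mutant replicate 1. Of 38 photoreceptor genes, 35 fell, 1 rose and 2 did not pass, with a median of -1.41 (camera adjusted p = 3.42e-36, or adjusted p = 0.229 with an estimated correlation). Besides rho, the falls included rod transducin gene gnat1 (-2.60 ± 0.14), arrestin gene sagb (-2.71 ± 0.12) and green cone opsin gene opn1mw1 (-1.47 ± 0.09), and the 1 that rose was the G protein subunit gene gnb1b (0.24 ± 0.08), a call that edgeR's quasi-likelihood test lost without sibling replicate 1 (adjusted p = 0.235) or 2 (adjusted p = 0.161). Of 24 exocrine pancreas genes, 21 fell, 1 rose and 2 did not pass, with a median of -1.61 (camera adjusted p = 9.82e-54, or adjusted p = 0.226 with an estimated correlation). Carboxypeptidase genes cpb1 (-2.30 ± 0.09) and cpa4 (-2.55 ± 0.10) and elastase gene ela2 (-2.05 ± 0.09) fell.

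**Figure D2:**
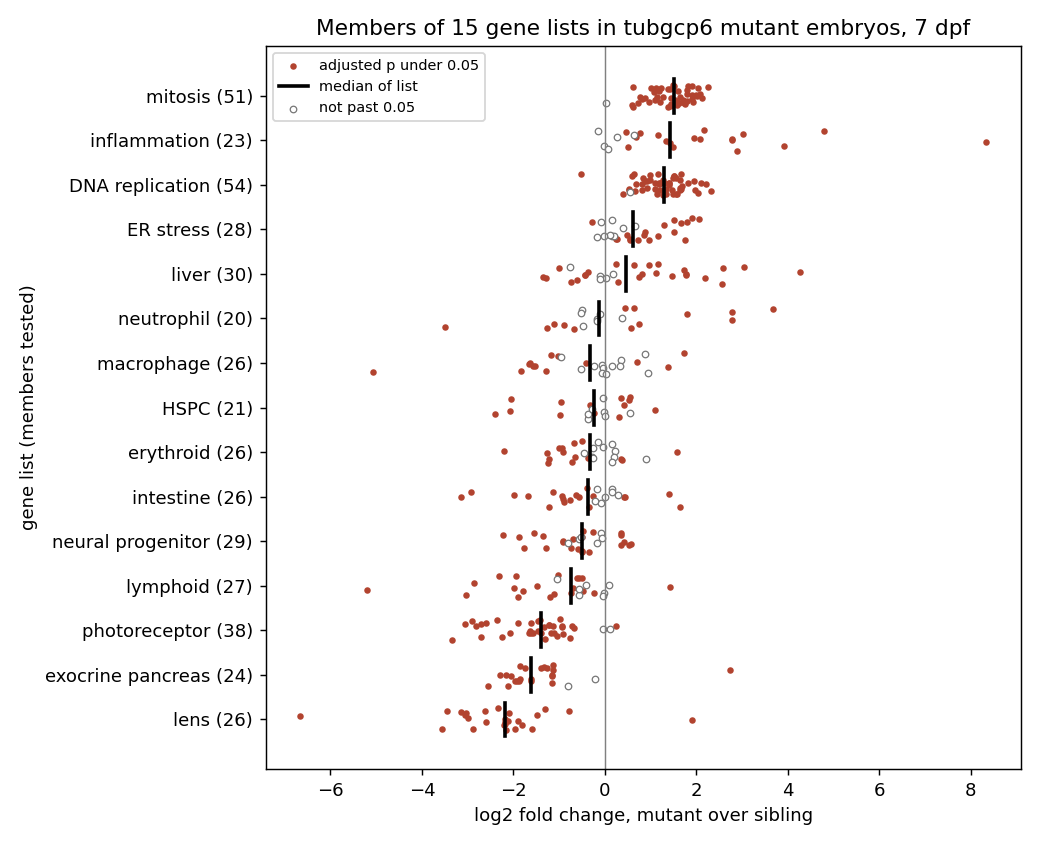
Log2 fold change (mutant over sibling, horizontal axis) of each tested member of 15 gene lists, with members past an adjusted p of 0.05 filled, other members open and the list's median as a black bar. Medians run from -2.19 for the lens list to 1.5 for the mitosis list.

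Other digestive, neural and metabolic lists moved less. Of 26 intestine genes, 15 fell and 4 rose (median -0.37, camera adjusted p = 3.43e-06, or adjusted p = 0.226 with an estimated correlation). The smallest p-values of edgeR's test in this list were those of the lysosomal digestion gene ctsl.1 (-2.92 ± 0.09) and the protein uptake genes lrp2b and cubn (-1.68 ± 0.12). Protein uptake was not tested as a set. Of 29 neural progenitor genes, 17 fell and 6 rose (median -0.51, camera adjusted p = 0.000802, or adjusted p = 0.229 with an estimated correlation), with the neurogenic factor genes neurod4 at -1.88 ± 0.12 and insm1a at -1.54 ± 0.14 and Notch ligand gene dla at -1.78 ± 0.16. The radial glia gene gfap (0.36 ± 0.08) and the progenitor gene her9 (0.52 ± 0.10) were among those that rose. Fewer genes of the list rose without sibling replicate 2, where gfap was at 0.32 and its call was lost. Of 29 neuron genes, 14 fell and 1 rose (median -0.19, camera adjusted p = 0.00922, or adjusted p = 0.408 with an estimated correlation), with vesicular glutamate transporter gene slc17a7a at -1.88 ± 0.23 and elavl3 at -0.64 ± 0.09. The fasting list that follows holds genes that fasting raises, such as igfbp1a, and genes that it lowers, such as srebf1. Its direction is therefore not that of a fasting response. Of 28 fasting response genes, 15 fell and 7 rose, or 15 and 8 adjusted over the list alone (median -0.30, camera adjusted p = 0.0461, or adjusted p = 0.329 with an estimated correlation), a call lost without sibling replicate 1 (adjusted p = 0.0836), where 4 rose, while 1 rose without sibling replicate 2; the lipid synthesis regulator gene srebf1 was at -0.99 ± 0.10 and igfbp1a, a gene that responds to insulin and fasting, at 0.67 ± 0.10.

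Cartilage and skin lists were higher. Of 25 cartilage and bone genes, 15 rose and 2 fell (median 0.55, camera adjusted p = 0.000283, or adjusted p = 0.408 with an estimated correlation; the call was lost with fry, adjusted p = 0.0514), with cartilage matrix genes matn1 at 1.28 ± 0.09 and col9a3 at 0.86 ± 0.09. Of 25 epidermis genes, 16 rose and 4 fell, or 16 and 5 adjusted over the list alone (median 0.32, camera adjusted p = 0.00189, or adjusted p = 0.408 with an estimated correlation), with claudin genes cldni at 1.31 ± 0.08 and cldne at 0.94 ± 0.09.

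The remaining 7 lists were not called by camera. Of 13 genes encoded by the mitochondrial genome, 8 rose and 0 fell, or 9 and 0 adjusted over the list alone, close to the threshold (median 0.26, camera adjusted p = 0.0517). This list was called higher without the filter on low counts (adjusted p = 0.0384), with the replicate block (0.0366), without mutant replicate 2 (0.00686) and without sibling replicate 1 (0.0493), and not without mutant replicate 1 or sibling replicate 2 (0.107 each). Only 3 of its genes rose without sibling replicate 1, and 1 without sibling replicate 2. ATP6 was at 0.50 ± 0.09. Of 23 endothelial genes, 9 rose, or 5 without sibling replicate 1, and 1 fell (median 0.16, camera adjusted p = 0.0926, but called higher by fry with an adjusted p of 0.0162), with scavenger receptor genes stab2 at 1.89 ± 0.12 and mrc1a at 1.23 ± 0.11. Of 29 muscle genes, 8 rose and 2 fell (median 0.06, camera adjusted p = 0.731). Of the 29, 4 rose without sibling replicate 1, 2 rose without sibling replicate 2, and 7 fell without mutant replicate 1 and likewise without mutant replicate 2. The muscle median was 0.009 without mutant replicate 1, 0.028 without sibling replicate 2 and 0.094 without sibling replicate 1. The parvalbumin gene pvalb1 was at 0.55 ± 0.10. Of 21 kidney genes, 3 rose and 6 fell (median 0.04, camera adjusted p = 0.483), with water channel gene aqp3a at 0.84 ± 0.08. Of 17 endocrine pancreas genes, 5 rose and 6 fell (median -0.20, camera adjusted p = 0.439), with glucagon gene gcgb at 1.70 ± 0.22 and neurod1, also a gene of retinal neurons, at -1.63 ± 0.09. Of 14 oligodendrocyte genes, 1 rose and 4 fell (median -0.07, or -0.026 without mutant replicate 2 and likewise without sibling replicate 1; camera adjusted p = 0.341), with mag at -0.98 ± 0.12. Of 41 ribosome biogenesis genes, 6 rose and 10 fell, or 5 and 10 adjusted over the list alone (median 0.005, camera adjusted p = 0.396), and 11 rose without mutant replicate 2, 3 without sibling replicate 1 and 1 without sibling replicate 2, with the helicase gene ddx21 at -1.04 ± 0.08. In the thrombocyte, kidney, endocrine pancreas and ribosome biogenesis lists the median, the mean and the direction given by camera did not all have the same sign. With 1 library left out the thrombocyte median ran from -0.356 (without mutant replicate 1) to 0.143 (without mutant replicate 2) and the kidney median from -0.085 (without mutant replicate 2) to 0.088 (without mutant replicate 1). The endocrine pancreas median ran from -0.206 (without sibling replicate 1) to 0.018 (without sibling replicate 2) and the ribosome biogenesis median from -0.029 (without mutant replicate 1) to 0.031 (without mutant replicate 2).

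Genes on the chromosome that carries tubgcp6 were compared with the rest of the genome because sorting embryos by genotype also sorts the linked parental haplotypes. That chromosome held 2.81% of the called genes and 3.05% of the tested genes with a known position (Fisher's exact test, two-sided p = 0.0963, odds ratio 0.865 with a 95% interval of 0.728 to 1.03). Genes higher in mutants were rarer there, at 2.47% of the genes called higher (Fisher's exact p = 0.0104). The odds ratio lay on the other side of 1 for genes lower in mutants, at 3.2% of them, and for the genes called by DESeq2, at 3.10%.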

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

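The glmTreat test and the 2-fold chromosome share were chosen after seeing the data. Leaving out 1 library at a time gave 2977 to 4840 genes higher and 2425 to 4680 lower, with both lowest counts without sibling replicate 2; without it 5402 genes were called, 5298 of them among the 8821 called with all libraries and in the same direction. With 1 library left in a group, the spread came from the other group alone. The chi-square per degree of freedom was 5.75 between the mutant libraries and 2.76 between the sibling libraries. The counts therefore also depend on which group kept 2 libraries, and other causes of their differences were not tested. DESeq2 called 6123 genes, 6100 of them shared in direction, and no shared call changed direction in any setting. Tested against a fold of 1.5, 1306 genes were higher and 824 lower, a stricter question by construction. For tubgcp6 the log2 fold change was -0.34 in DESeq2, short of the threshold (adjusted p = 0.0585, against 0.00273 to 0.267 over all alternatives), and -0.39 to -0.25 with 1 library left out; the cause was not tested. For the 124 other genes named, 1357 values under the alternatives kept their direction and side of the threshold, 6 lost the call (gata2b, gnb1b, ddit3 and gfap, each without a sibling library) and 1 gained it (runx1 without mutant replicate 1). Most of these named genes had been picked for large changes or small p-values in these data, which favours stable calls. Camera with an estimated correlation called 0 lists higher and 0 lower, and the estimate rests on 4 libraries. It was above the preset 0.01 for most called lists, up to 0.477 for the photoreceptor list. For the intestine (-0.039) and lymphoid (-0.016) lists it was below, so a higher correlation between genes cannot explain their lost calls. When the correlation is estimated, camera takes its degrees of freedom from the 4 libraries, which by itself limits how small a p can be. With fry, 16 of the 19 called lists passed, and the neutrophil, handling stress and cartilage and bone lists did not. Fry also called the gamma-tubulin, endothelial and interferon lists. It does not weigh a list against other genes, and 43.89% of the tested genes were called. A call by fry alone therefore does not set a list apart. The mean of the HSPC list lay between -0.52 (no filter) and -0.26 (without mutant replicate 1) and the list passed camera under no setting, nor fry's test in 1 direction. The share of calls on the chromosome of tubgcp6 was 2.47% among higher, 3.2% among lower, 3.10% among DESeq2's and 3.09% among 2-fold calls, against 3.05% of tested genes; the 95% interval of the odds ratio left out 1 for higher genes (0.608 to 0.941) and held it for the others, and the cause was not tested. Whether the replicate numbers pair the libraries cannot be told. The deviations of same-numbered libraries from their group means correlated at 0.0182 across genes, but with 2 pairs this cannot exclude shared clutches. The replicate block gave 4828 genes higher and 4521 lower. Scaling moved the median log2 fold change of all genes from 0.0072 to -0.0044 at most.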

Other observations

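The tests on name families, on the neighbours of tubgcp6, and all tests in the last 3 paragraphs except that of rod against cone genes were chosen after the result was seen. Permutation p-values and bootstrap intervals in those paragraphs treat the genes of a list as independent units. They measure spread between genes and not between embryos or libraries. Genes grouped by the letters that begin their symbol, in 316 families of at least 8 tested members, were also tested with camera; 21 families passed an adjusted p of 0.05, 12 higher and 9 lower, and 0 passed with an estimated correlation (lowest adjusted p = 0.977). The run with an estimated correlation has the same limit here, as its degrees of freedom come from the 4 libraries. None of the 21 medians changed sign under the other scalings. All genes named in this paragraph and the next were picked after their values were seen. Actin-nucleating Arp2/3 complex genes were higher, with 9 of 10 arpc genes rising (median 0.75, adjusted p = 7.63e-06), among them arpc5a by 1.67 ± 0.10 (SE) and arpc1a by 1.02 ± 0.09. Of 21 matrix metalloproteinase genes 11 rose and 2 fell (median 0.51, adjusted p = 0.000138), with mmp13b at 3.50 ± 0.32, mmp13a at 2.77 ± 0.19 and mmp2 at 1.93 ± 0.08. Of 10 chemokine genes of the cxcl family 6 rose and 0 fell (median 0.85, adjusted p = 0.00311), with cxcl18b at 3.16 ± 0.19 and cxcl8b.3 at 2.25 ± 0.24. Of 14 fkbp genes, which encode prolyl isomerases, 10 rose and 2 fell (median 0.65, adjusted p = 0.0164), with fkbp9 at 2.4 ± 0.15 and fkbp7 at 1.92 ± 0.18.

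Among families that were lower, all 28 gamma-crystallin M genes fell (median -1.82, adjusted p = 6.87e-53), a set of similar copies whose single values are uncertain. Of 20 opsin genes 13 fell and 0 rose (median -1.05, adjusted p = 7.63e-06), among them the non-visual opsin gene opn6b by 1.91 ± 0.16. Of 23 calcium channel subunit genes of the cacna family 16 fell and 0 rose (median -0.57, adjusted p = 0.000943), with cacna1fb at -1.01 ± 0.13, and of 52 protocadherin genes 24 fell and 0 rose (median -0.42, adjusted p = 0.00218), with pcdh8 at -1.45 ± 0.14. Among the 40 tested genes nearest to tubgcp6, 20 on each side, 7 were higher and 12 lower, a called share of 47.5% against 43.9% of the other tested genes (Fisher's exact test, two-sided p = 0.637, odds ratio 1.16 with a 95% interval of 0.588 to 2.26). The nearest tested gene on one side, plxnb2b, was at -1.27 ± 0.13. Most called neighbours on the side of plxnb2b were lower, and most on the other side were higher. This split was seen after the fact and was not tested.

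Mitosis and DNA replication genes were higher in mutants in 102 of 105 cases. A scaling error would shift all genes alike and leave these level with the rest. The list medians lay above the median of the other tested genes by 1.495 (bootstrap 95% interval 1.367 to 1.615) for mitosis and 1.283 (1.148 to 1.475) for replication, a gap that a shift common to all genes cannot give. Camera had already called both lists against the other genes, so these values restate that result and are no separate test. A uniform delay of development would keep neural progenitor genes higher, but 6 of 29 rose and 17 fell (median -0.51), so they did not move as 1 class; lower lens, rod and pancreas genes and higher lin28a go with a delay, while lower lin28b and embryonic globin gene hbbe2 do not, so it cannot be excluded. A hold-up of cells in mitosis, a candidate explanation for a mutant of a spindle gene, predicts a stronger rise of mitosis than of replication genes; the medians differed by 0.212 (permutation p = 0.101), so it cannot be told apart from a larger share of cycling cells. These remain open, as does any effect of the unstated sibling genotypes, which was not tested.

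Lens, photoreceptor and exocrine pancreas genes were lower in mutants. Against the median of the other tested genes, the list medians lay at -2.194 (bootstrap 95% interval -2.742 to -2.045) for lens, -1.416 (-1.629 to -1.167) for photoreceptor and -1.617 (-1.895 to -1.169) for exocrine pancreas. A shift common to all genes cannot give such a gap. Here too camera had already called the lists against the other genes, so the values are no separate test. A smaller share of the photoreceptor layer alone would lower rod and cone genes alike. The median was -2.65 over 12 rod genes and -1.18 over 13 cone genes, a difference of -1.471 (permutation p = 0.00166, or 0.00498 adjusted over the 3 permutation tests of this part). This p can be too small where genes move together, and the estimated correlation in the photoreceptor list was 0.477. For these genes in these libraries, the medians argue against a smaller layer as the whole source. Rods may be affected more than cones, as a hypothesis found on these data; fewer cells and less RNA per cell were not separated.

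Lymphoid genes were lower in mutants. If leukocytes of every kind were fewer, lymphoid and myeloid genes would fall alike. The medians were -0.73 over 27 lymphoid and -0.205 over 44 neutrophil and macrophage genes not on the inflammation list, a difference of -0.525 (permutation p = 0.0518, or 0.0777 adjusted). Of the 44 genes 16 fell and 9 rose, from -5.07 for csf1rb to 3.68 for lect2l, so their median covers genes that moved both ways. The explanation cannot be excluded. Lower thymic epithelium cannot be told apart either, because the median of its 6 genes was 0.116 with a bootstrap 95% interval of -0.54 to 0.80, and lay between -0.191 and 0.429 with 1 library left out. A loss that begins in HSPCs was not tested separately. Of the HSPC genes 6 rose and 8 fell, and the largest changes were falls, among them gata2b (-2.40) and itga2b (-2.07) at low counts. RNA of whole embryos does not separate HSPCs from other cells that express these genes.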
